A study of Homo sapiens with 6 samples.

How the data were processed

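Gene expression was measured on 6 Affymetrix gene-level arrays of MDA-468.shp53, a human breast cancer cell line grown in 3-dimensional culture for 8 days. The line name points to MDA-MB-468 cells, an established line with mutant p53, that carry a short hairpin RNA against p53. Cells were grown with or without doxycycline, the drug used to switch on such hairpins, in 3 independent experiments, with 1 array of each group per experiment. Per the labels' protocols, total RNA was isolated on silica columns, amplified with a whole-transcript kit, fragmented and end-labelled with biotin.

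The values deposited by the authors are on a log2 scale and come from the Robust Multichip Average (RMA), which corrects background, brings the arrays to a common distribution and summarises the probes of each probe set. The submitters' processing notes name RMA and R 2.11.1. A deposited workbook by the authors holds the same log2 values (largest difference 5.0e-09), with their mean per group, the difference of the means and a p-value per probe set. Its value columns carry no replicate number, so it was used without pairing. Matched by values, the culture codes in their names pair the arrays as the replicate numbers do. Depth has no counterpart on arrays, and the number of arrays limits the precision. The median log2 value per array lay between 7.45 and 7.56.

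The table held 33297 probe sets, of which 976 were empty on each array, among them 686 with a gene symbol. The file marked 4428 as controls, 4295 of them with values, and these were kept out of the comparisons. The remaining 28026 probe sets were tested, with no filter on dim probe sets. Gene names came from the accessions and symbols of the file, updated through the RefSeq gene table of assembly GRCh38.p14, which was used for names alone. Accessions named 18098 tested probe sets, current symbols 897 and older symbols 740, and 1087 kept the name in the file. Another 578 matched several genes and 6623 had no symbol, so none of these was named. On the mitochondrial chromosome, 3 further probe sets carried symbols of nuclear genes and were left unnamed. This gave 20822 probe sets with 1 gene, for 19898 genes. Of these, 723 had more than 1 probe set, and the probe set with the highest mean over the 6 arrays stood for the gene. Coordinates are those of the file, which match NCBI build 36 by the versions of its chromosome accessions.

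Doxycycline-treated arrays were compared with doxycycline-free arrays in limma 3.58.1 under R 4.3.3 (lmFit and eBayes), with the experiment as a term, and with Benjamini-Hochberg adjustment over the 28026 probe sets and a threshold of 0.05. Changes are treated minus untreated on the log2 scale, with moderated standard errors (SE). Pairing came from the design text of the series, which describes 3 independent experiments and a paired test per probe. As a check, the deviations of the 2 arrays of an experiment from their group means correlated at 0.482, 0.165 and 0.0993 over all probe sets for experiments 1, 2 and 3. The methods' t-test, paired over the experiments and at the 1% level of the design text, was run on the same values. Its p-values differed from those in the authors' deposited table by at most 1.75e-07. An exact sign-flip test of 3 pairs cannot give a two-sided p below 0.25.

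Before the data were examined, 35 gene lists, the tests, the alternatives and the rule for the genes named below were fixed. Each list was tested with camera in limma at a preset correlation of 0.01 between genes, with camera at a correlation estimated from the data, and with fry, each adjusted over the 35 lists. Camera asks whether a list moved against the other genes. Fry asks whether its genes moved on balance in 1 direction and compares them with no other genes. Genes to be named were the 10 largest rises and 10 largest falls among probe sets with 1 gene that passed the threshold with the same sign in all 3 experiments, and each measured gene of the mevalonate and sterol lists. From each other list came up to 4 genes with the smallest p among those that passed, or the 2 with the smallest p if none did. Results for some of these genes and for 1 of the lists are not reported here. Counts called adjusted over the list alone used the adjustment within that list. Gene groups defined only after the values were seen appear in the closing observations and are named as such there.

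The procedure was tested on simulated data for the treated against untreated comparison, with 28026 probe sets, mean and spread taken from the arrays, and 50 probe sets changed at each size. It recovered 18.0% of changes of 0.5 on the log2 scale, 96.0% of changes of 1 and 100.0% of changes of 2 and of 3, with 1 false call among 158. The methods' t-test called 0 of these after Benjamini-Hochberg adjustment. Far fewer probe sets were called in the simulation (158) than in the data (3580), so the adjusted threshold was stricter there. The recovered share of small changes is therefore not that of the data. A simulated list of 28 genes, each lowered by 0.5, reached an adjusted p of 7.81e-45 with camera and 0.034 with fry, but 0.378 with camera at an estimated correlation, which here rests on 2 residual degrees of freedom. Noise was drawn independently for each probe set, so the simulation cannot show how camera at the preset correlation behaves on correlated genes.

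Alternatives were a fit without the experiment term, the methods' t-test, a fit with a trended and robust variance, removal of the dimmest 25% or 50% of probe sets, a repeated quantile normalization, equal medians of all arrays, the workbook values, probe sets with 1 gene alone, and each experiment left out in turn. List results were also computed with an estimated correlation, with fry and with the mean of all probe sets of a gene. The count of changed probe sets was also taken with a 1.5-fold minimum and at an adjusted p of 0.10. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15, and tables were joined with pandas 2.3.3.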

Results

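The series compared MDA-468.shp53 breast cancer cells grown in 3-dimensional culture for 8 days with and without doxycycline, to ask how the p53 hairpin changes gene expression under conditions in which mammary cells form acini. Each group held 3 arrays, 1 from each of 3 independent experiments. Arrays of different groups correlated at 0.983 to 0.991 over all probe sets, and arrays within a group at 0.991 to 0.997. The leading principal component held 52.7% of the variance and separated treated from untreated arrays. The next, with 24.0%, set experiment 1 apart from the others. Arrays of cells with doxycycline and without the hairpin were not analysed here, so each change below is that of hairpin and drug together.

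IGFBP5, a binding protein of insulin-like growth factors, had the largest fall, 13.3-fold, from 10.43 ± 0.10 to 6.69 ± 0.09 (log2 change -3.74, SE 0.096, n = 3 each, limma adjusted p = 9.93e-06). EFEMP1, an extracellular matrix protein, fell 6.92-fold. CP, the copper carrier ceruloplasmin, fell 6.80-fold, SCGB2A2, the secretoglobin mammaglobin, 6.53-fold, and KDR, a receptor of vascular endothelial growth factor, 5.70-fold. SAA1 and S100A8, which belong to inflammatory responses, fell 5.33-fold and 5.32-fold. The remaining genes of this group were H2BC14, a histone H2B gene (6.99-fold), and RNU5D-1 and RNU5E-1, which encode U5 RNA of the spliceosome (7.63-fold and 5.81-fold). Members of these multigene families are near-identical in sequence, so their single values are uncertain.

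CYP1A1, a cytochrome P450 of xenobiotic metabolism, had the largest rise among probe sets that stand for a gene, 8.84-fold, from 9.08 ± 0.69 to 12.22 ± 0.18 (log2 change 3.14, SE 0.2, n = 3 each, limma adjusted p = 0.000322). The endoplasmic reticulum chaperone CLGN rose 8.81-fold, SH3BGR 4.25-fold, NIBAN1, which is known as a stress-responsive gene, 4.18-fold, and the lysosomal membrane protein LAMP3 4.08-fold. CCN3, a matricellular protein, rose 3.74-fold, the microtubule-associated protein MAP1B 3.72-fold, the uridine phosphorylase UPP1 3.72-fold, the Notch ligand JAG1 3.48-fold and CTH, which makes cysteine from cystathionine, 3.27-fold. With the trended and robust variance, CTH, H2BC14 and RNU5E-1 no longer passed (adjusted p = 0.0533, 0.0686 and 0.0649).

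**Figure D1:**
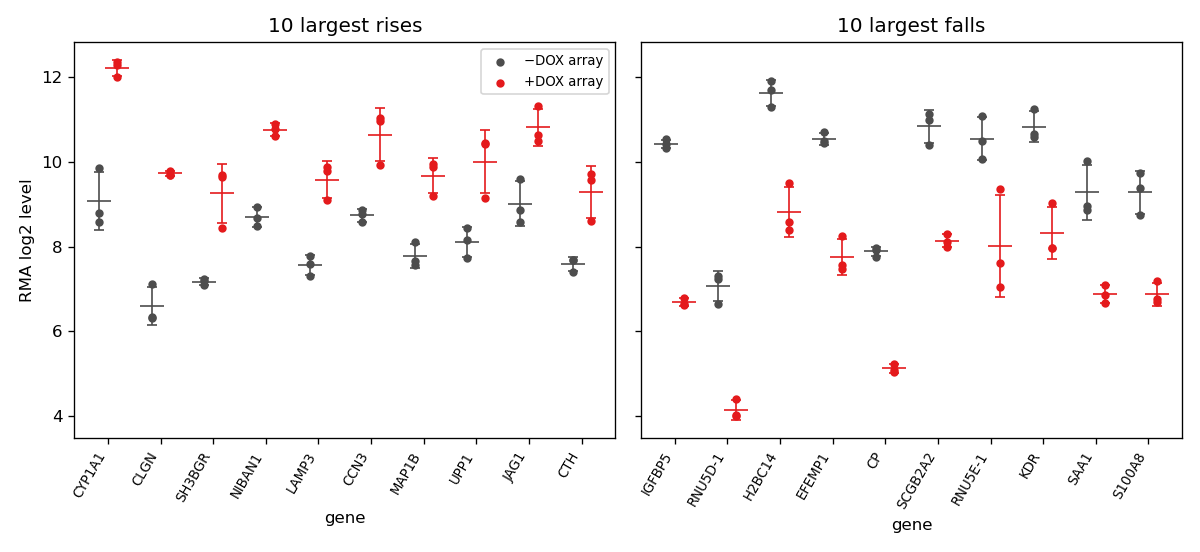
RMA log2 level (y axis) of the 10 genes with the largest rises and the 10 with the largest falls (x axis). Points are arrays, grey without and red with doxycycline, and bars the mean ± SD of 3 arrays. IGFBP5 stood at 10.43 without and 6.69 with doxycycline.

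Over the whole array, 3580 of 28026 probe sets passed the threshold, 12.8%, of which 1721 rose and 1859 fell. They stood for 3183 of 19898 genes, 1592 that rose and 1591 that fell. Larger changes were mostly falls: of 342 probe sets with at least a 2-fold change, 251 fell. At an unadjusted p under 0.01 limma found 4160 probe sets, against 280.26 by chance. The methods' t-test found 1165 at that level, 808 of them among the 3580 probe sets past the limma threshold, and 0 after adjustment, with 4449 at an unadjusted p under 0.05. Without the experiment term 2409 probe sets passed, with rises at 1109. Leaving out experiment 2 gave 1909 and leaving out experiment 3 gave 1355.

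The mevalonate pathway, which builds isoprenoid precursors from acetyl-CoA and is named in the title of the series, was lower with doxycycline. Of 10 measured genes, 7 fell, 1 rose and 2 did not pass, with the same counts adjusted over the list alone. HMGCS1, the synthase that makes HMG-CoA, fell from 12.15 ± 0.09 to 10.64 ± 0.11 (log2 change -1.51, SE 0.089, n = 3 each, limma adjusted p = 0.000277). MVK changed by -1.21 (SE 0.087), MVD by -1.06 (SE 0.093), ACAT2 by -1.20 (SE 0.11), IDI1 by -0.86 (SE 0.1) and FDPS, which makes farnesyl diphosphate, by -0.74 (SE 0.081). GGPS1, which turns farnesyl into geranylgeranyl diphosphate, rose by 0.36 (SE 0.091). Its call was lost without the experiment term (adjusted p = 0.196) and without experiment 2 or 3 (up to 0.175). PMVK (0.19, SE 0.096) and IDI2 (-0.12, SE 0.11) did not pass. The list median was -0.96 (camera adjusted p = 3.04e-06 and fry adjusted p = 0.0251, but adjusted p = 0.401 with an estimated correlation). Here and below, the version with an estimated correlation rests on 2 residual degrees of freedom and also missed the simulated list. The study chose this pathway on these arrays, so neither count is independent evidence of its direction.

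Of 13 measured genes that make squalene and turn it into cholesterol, 11 fell and none rose, with 12 falls adjusted over the list alone, and the median was -0.65 (camera adjusted p = 3.4e-10, but adjusted p = 0.401 with an estimated correlation). The cyclase LSS changed most, by -1.28 (SE 0.097), and TM7SF2 (-1.02, SE 0.11), EBP (-0.85, SE 0.097), DHCR7 (-0.79, SE 0.081) and the epoxidase SQLE (-0.76, SE 0.085) fell less. NSDHL (-0.65), CYP51A1 (-0.57), FDFT1 (-0.56), SC5D (-0.53) and LBR (-0.46) also fell. LBR did not pass without the experiment term (adjusted p = 0.0618) or with equal array medians (0.0503), and SC5D and LBR did not pass with some experiment left out (up to 0.1 and 0.174). MSMO1 (-0.48, adjusted p = 0.0630) and FAXDC2 (0.06) did not pass, though MSMO1 did in the settings that test fewer probe sets (0.0219 to 0.0323).

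**Figure D2:**
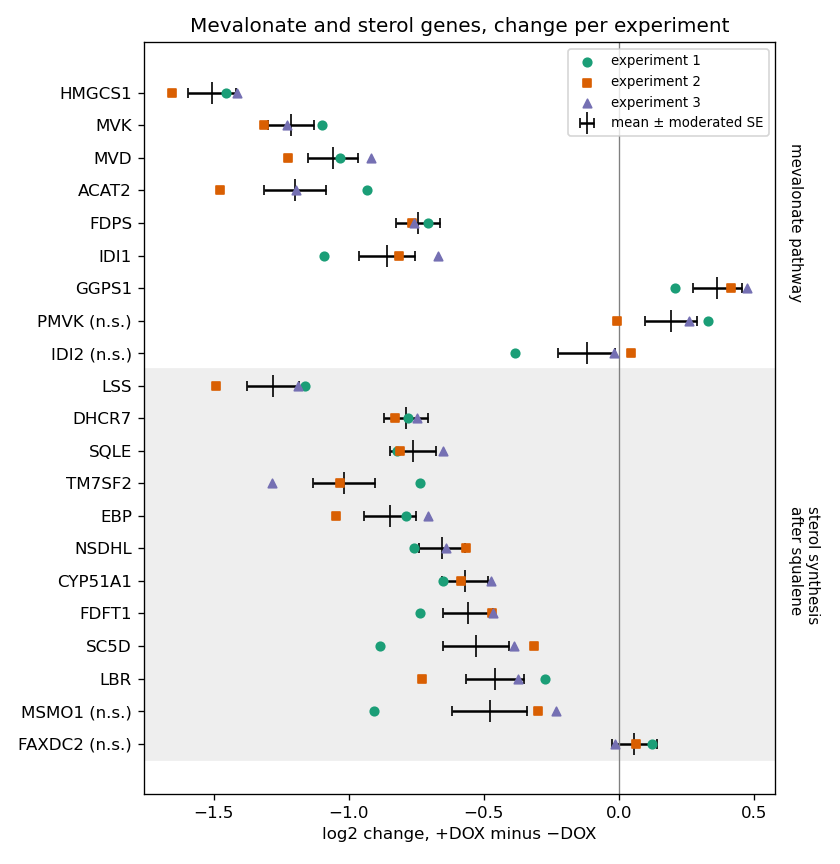
Log2 change with doxycycline (x axis) of 21 mevalonate and sterol genes (y axis). Symbols mark the 3 experiments, bars the mean ± moderated SE, and n.s. a gene not past an adjusted p of 0.05. HMGCS1 had the largest fall among these (-1.51) and GGPS1 the largest rise (0.36).

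Among regulators and uptake genes of cholesterol, INSIG1, which holds the SREBP complex in the endoplasmic reticulum and is itself an SREBP target, fell by 1.55 (SE 0.09) and TMEM97 by 0.99 (SE 0.081). Of 14 measured, 6 fell and 8 did not pass, against 7 falls and 1 rise adjusted over the list alone. The median was -0.19 (camera adjusted p = 0.0174, but adjusted p = 0.45 with an estimated correlation, and 0.201 on the statistics of the methods' t-test). Among genes of fatty acid synthesis and desaturation 11 of 17 fell and 1 rose, with 13 falls and 1 rise adjusted over the list alone. The desaturases FADS2 (-1.80, SE 0.086) and FADS1 (-0.94, SE 0.085), the synthase FASN (-1.37, SE 0.11) and ACLY (-0.85, SE 0.082), which supplies cytosolic acetyl-CoA, led them. The list median was -0.47 (camera adjusted p = 5.34e-08, but adjusted p = 0.401 with an estimated correlation).

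**Figure D3:**
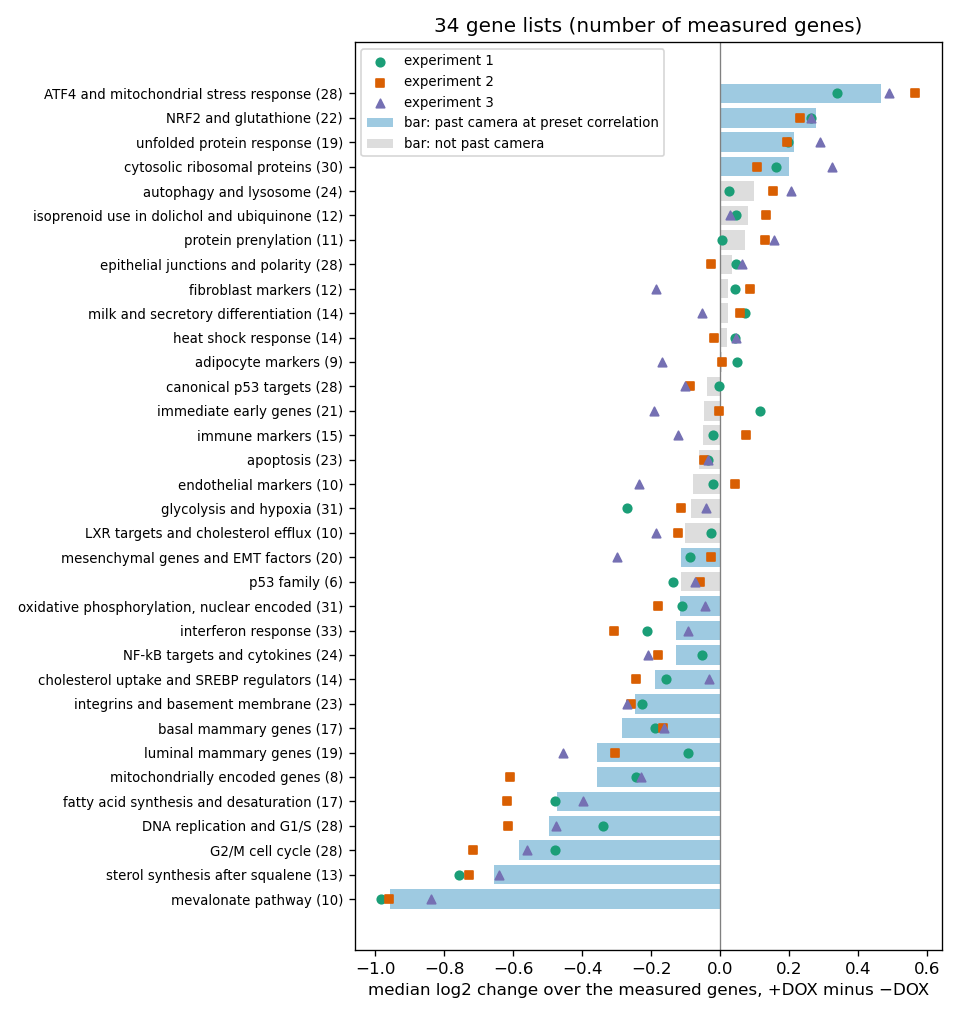
Median log2 change with doxycycline (x axis) of the measured genes of 34 lists (y axis, number of genes in brackets). Bars give the median of the gene changes over all experiments and symbols the median within each of the 3 experiments, with blue bars past camera at an adjusted p of 0.05 and a preset correlation. The mevalonate pathway has the lowest median (-0.96) and the ATF4 list the highest (0.47).

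Lists of isoprenoid use and cholesterol efflux were not called. Of 11 genes of protein prenylation 4 rose and 1 fell (4 and 2 adjusted over the list alone), and camera made no call (adjusted p = 0.238). RABGGTB (0.82, SE 0.091) and PGGT1B (0.72, SE 0.09), subunits of geranylgeranyl transferases, rose. PCYOX1, which breaks down prenylcysteine, fell by 0.66 (SE 0.092). FNTA, a subunit shared by the farnesyl and geranylgeranyl transferases, rose by 0.75, a call lost without the experiment term (adjusted p = 0.0504). Of 12 genes that use isoprenoids for dolichol, ubiquinone and tRNA, 4 rose and none fell (4 and 2 adjusted over the list alone), with no call from camera (adjusted p = 0.351). TRIT1 rose most, by 0.67 (SE 0.12), but not past the threshold without experiment 3 (adjusted p = 0.0775). In the LXR and cholesterol efflux list 2 of 10 fell and none rose, against 4 falls and 2 rises adjusted over the list alone (camera adjusted p = 0.262). LPCAT3, which remodels phospholipids, fell by 0.76 (SE 0.084). CCN2 fell 4.79-fold and ANKRD1 1.77-fold, both known YAP/TEAD targets.

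Canonical transcriptional targets of wild-type p53 were not called as a group. Of 28 measured, 3 rose, 4 fell and 21 did not pass (3 and 7 adjusted over the list alone). The median was -0.04 (camera adjusted p = 0.199), and fry called the list lower (adjusted p = 0.0434). With equal array medians the list median was 0.0011. That scaling moved all probe sets alike by 0.04, so the turn of sign says nothing about these genes. PLK2 (-1.06, SE 0.091), the translesion polymerase gene POLH (-0.86, SE 0.081) and the cell cycle inhibitor CDKN1A (-0.65, SE 0.098) fell. CDKN1A missed the threshold without experiment 3 (adjusted p = 0.0502). SESN2, which is also induced by ATF4, rose by 0.63 (SE 0.085). In the p53 family list, of 6 genes, MDM4 rose by 0.67 (SE 0.14) and TP73 fell by 0.39 (SE 0.084), the same counts as adjusted over the list alone, and both calls were lost with some experiment left out (adjusted p up to 0.0975 and 0.111). Camera made no call on that list (adjusted p = 0.647).

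Most genes of the proliferation lists fell with doxycycline. In the G2/M list 23 of 28 fell and none rose, with 26 falls adjusted over the list alone. The mitotic kinesin KIF20A fell by 1.88 (SE 0.15), DLGAP5 by 1.13 (SE 0.1), the proliferation marker MKI67 by 0.98 (SE 0.092) and the mitotic kinase CDK1 by 0.87 (SE 0.081). The median was -0.58 (camera adjusted p = 1.11e-16 at the preset correlation of 0.01, but adjusted p = 0.401 with the estimated correlation of 0.399). Of 28 genes of DNA replication and the G1/S step 19 fell and none rose, against 23 falls and 1 rise adjusted over the list alone. Cyclin E2 (CCNE2, -1.65, SE 0.13), the ribonucleotide reductase subunit RRM2 (-1.56, SE 0.18), UHRF1 (-1.30, SE 0.15) and GINS2 (-0.99, SE 0.087) had the smallest p. The median was -0.50 (camera adjusted p = 2.56e-13, but adjusted p = 0.413 with an estimated correlation and 0.0614 with fry).

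Genes of cell adhesion and mammary identity fell in part. Of 23 integrin and basement membrane genes 9 fell and none rose, with 13 falls adjusted over the list alone. The integrin ITGB4 of hemidesmosomes changed by -1.38 (SE 0.17), the laminin chain LAMB1 by -0.84 (SE 0.1) and ITGB6 by -0.63 (SE 0.081). The median was -0.25 (camera adjusted p = 1.11e-06, but adjusted p = 0.401 with an estimated correlation). Luminal genes showed 8 falls and 2 rises among 19 (11 and 2 adjusted over the list alone), with MUC1 at -1.25 (SE 0.1), KIT at -0.86 (SE 0.094), KRT8 at -0.63 (SE 0.089) and SPDEF at -1.40 (SE 0.2). SPDEF missed the threshold without experiment 3 (adjusted p = 0.0555). The luminal median was -0.36 (camera adjusted p = 0.000246, but adjusted p = 0.401 with an estimated correlation and 0.0614 with fry).

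Basal genes showed 7 falls and 1 rise among 17, against 9 and 4 adjusted over the list alone, led by MME (-1.52, SE 0.081), CAV1 (-1.15, SE 0.087) and P-cadherin (CDH3, -0.76, SE 0.081). Their median was -0.28 (camera adjusted p = 0.0327, but adjusted p = 0.45 with an estimated correlation and 0.0894 without the experiment term). That call was also lost without experiment 2 (adjusted p = 0.0582) and on the statistics of the methods' t-test (0.167). Of 20 mesenchymal genes 3 fell and none rose (5 falls adjusted over the list alone). TGFB2 (-1.07, SE 0.081) and TGFB1 (-0.85, SE 0.13) encode growth factors of the TGF-beta family. FN1 (-0.43, SE 0.11) was the third, and its call was lost without the experiment term (adjusted p = 0.371), with other scalings (0.068 and 0.0672) and with any experiment left out (up to 0.165). The mesenchymal median was -0.11 (camera adjusted p = 0.00694, but adjusted p = 0.45 with an estimated correlation, 0.0884 with fry and 0.0548 on the statistics of the methods' t-test). Epithelial junction and polarity genes went both ways, with 4 rises and 4 falls among 28 (6 and 5 adjusted over the list alone, camera adjusted p = 0.862). CLDN4, a tight junction claudin, fell by 1.01 (SE 0.083), whereas CTNNA1, which links cadherins to actin, rose by 0.79 (SE 0.083).

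Of 28 genes of the ATF4 and mitochondrial stress list 18 rose and none fell, with 23 rises adjusted over the list alone. The cytokine GDF15 rose by 1.62 (SE 0.16), the amino acid transporter SLC7A5 by 1.13 (SE 0.12), the pseudokinase TRIB3 by 1.10 (SE 0.097) and STC2 by 1.09 (SE 0.094). The median was 0.47 (camera adjusted p = 4.92e-13, but adjusted p = 0.401 with an estimated correlation). In the unfolded protein response list 8 of 19 rose and none fell (9 rises adjusted over the list alone), with SEL1L at 0.88 (SE 0.086), ATF6 at 0.71 (SE 0.1), HYOU1 at 0.63 (SE 0.088) and DNAJB9 at 0.61 (SE 0.083). That median was 0.21 (camera adjusted p = 0.000156, but adjusted p = 0.401 with an estimated correlation). Among NRF2 and glutathione genes 8 of 22 rose and none fell, against 12 rises and 1 fall adjusted over the list alone. AKR1C3 rose by 1.35 (SE 0.13), GCLM and GCLC, the subunits of the enzyme that limits glutathione synthesis, by 1.06 (SE 0.11) and 0.83 (SE 0.084), and TXNRD1 by 0.92 (SE 0.087). Their median was 0.28 (camera adjusted p = 5.28e-06, but adjusted p = 0.401 with an estimated correlation).

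Of 30 cytosolic ribosomal protein genes 5 rose and none fell (7 rises adjusted over the list alone), with RPL30 at 0.39 (SE 0.085), a call lost without the experiment term (adjusted p = 0.127) and with any experiment left out (up to 0.113). The median was 0.20 (camera adjusted p = 0.000165, but adjusted p = 0.45 with an estimated correlation and 0.106 with fry). Of 8 mitochondrially encoded genes 3 fell and none rose (7 falls adjusted over the list alone). ND6 changed by -0.66 (SE 0.095), ND3 by -0.93 (SE 0.11) and ND2 by -0.79 (SE 0.14), the last pair of calls being lost without the experiment term (adjusted p = 0.0529 and 0.116). Their median was -0.36 (camera adjusted p = 5.91e-05, but adjusted p = 0.45 with an estimated correlation and 0.0923 with fry). Nuclear genes of oxidative phosphorylation had 3 falls, led by NDUFA2 (-0.77, SE 0.083), and 1 rise among 31, the same adjusted over the list alone. The median was -0.12 (camera adjusted p = 0.0428, but adjusted p = 0.45 with an estimated correlation and 0.0515 without the experiment term). Glycolysis and hypoxia genes were not called (3 rises and 6 falls among 31, the same adjusted over the list alone, camera adjusted p = 0.0712), except without experiment 3, where camera called them lower (adjusted p = 0.00558). HK2, which starts glycolysis, rose by 0.83 (SE 0.098) and CA12 fell by 0.67 (SE 0.091).

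Of 33 interferon response genes 12 fell and 3 rose (14 and 4 adjusted over the list alone). The antiviral synthetases OAS1 (-1.38, SE 0.12) and OAS3 (-0.98, SE 0.096), IFI6 (-1.12, SE 0.11) and SAMD9 (-0.96, SE 0.089) fell. The median was -0.13 (camera adjusted p = 0.00101, but adjusted p = 0.401 with an estimated correlation). Of 24 NF-kB targets and cytokines 7 fell and none rose, the same adjusted over the list alone. The chemokine CXCL8 fell by 1.69 (SE 0.13), TNFAIP3 by 0.98 (SE 0.1) and NFKBIA by 0.87 (SE 0.1), the latter pair being feedback inhibitors of NF-kB. Their median was -0.13 (camera adjusted p = 0.00039, but adjusted p = 0.401 with an estimated correlation).

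Camera called 18 of the 35 lists in all, and 0 with an estimated correlation, where 2 had an unadjusted p under 0.05. That version has little power here, as the simulated list with each gene lowered reached a camera adjusted p of only 0.378 with it. Its lack of calls therefore decides nothing about these lists. The estimated correlation was -0.0017 for sterol synthesis, below the preset 0.01, so correlation between its genes does not account for the lost call of that list. The estimate was 0.277 for the ATF4 list, 0.399 for G2/M, 0.461 for DNA replication and 0.829 for mitochondrially encoded genes. If these estimates hold, camera p-values at the preset 0.01 are too small for the latter lists. Fry called 13. Apoptosis genes went both ways (6 rises and 4 falls among 23, 7 and 4 adjusted over the list alone, camera adjusted p = 0.927), with BCL2 at 0.75 (SE 0.082) and APAF1 at -0.75 (SE 0.082). Autophagy and lysosome genes had 6 rises and 2 falls among 24 (7 and 3 adjusted over the list alone, camera adjusted p = 0.168). Immediate early genes had 5 rises and 4 falls among 21 (5 and 5 adjusted over the list alone, camera adjusted p = 0.777), with KLF4 at 0.90 (SE 0.091) and EGR1 at -1.02 (SE 0.12). The heat shock list had 2 rises and 1 fall among 14, the same adjusted over the list alone (camera adjusted p = 0.717). HSPH1 rose by 0.54 (SE 0.095), a call lost without experiment 3 (adjusted p = 0.0682). XDH was the single fall among 14 milk and secretion genes (-0.34, SE 0.088), with none adjusted over the list alone, and its call was lost without the experiment term (adjusted p = 0.259). That list was not called (camera adjusted p = 0.958).

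Lists of markers of other cell types had mean log2 levels of 6.51 to 6.95, below the array medians, and were not called. Fibroblast markers had 2 falls among 12 (FBLN1 at -0.43, SE 0.087, and FAP at -0.36, SE 0.086), both lost with some experiment left out (adjusted p up to 0.108 and 0.151), and a camera adjusted p of 0.647. Endothelial markers had 1 fall among 10, KDR (-2.51, SE 0.11), with a camera adjusted p of 0.0789 that passed without experiment 2 (0.0316). Immune markers had 1 fall among 15, CD14 (-0.65, SE 0.083), lost without the experiment term (adjusted p = 0.1), and a camera adjusted p of 0.733. Adipocyte markers had 1 rise among 9, PPARG (1.10, SE 0.17), lost without the experiment term (adjusted p = 0.131), and a camera adjusted p of 0.927. The counts of these 4 lists were the same adjusted over the list alone.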

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

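The test of the control probe sets in this part was chosen only after the values were seen. Among 4295 probe sets that the file marks as controls and that no comparison used, 114 had a limma unadjusted p under 0.01, 2.65% of them and above the 42.95 that chance gives. The share among tested probe sets was 14.8%. With adjustment over the controls 0 passed, and 443 had an unadjusted p under 0.05, against 214.75 by chance. The methods' t-test gave 98 at the 1% level.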

How the results depend on the processing

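None of these alternatives was added after the values were seen. The mevalonate median stayed below 0, and the counts of changed probe sets and of lists stayed within 1.5 times of 3580, 4160 and 18, except as follows. With the methods' t-test 1165 probe sets passed the 1% level, and 0 passed adjustment (0 rises and 0 falls), since that test has 2 residual degrees of freedom per probe set. Without the experiment term, on matrix or workbook values, rises numbered 1109. A 1.5-fold minimum left 1405 probe sets, 560 that rose and 845 that fell, whereas an adjusted p of 0.10 gave 4958, which is within 1.5 times. With an estimated correlation the mevalonate median of -0.96 had an adjusted p of 0.401 (1.56e-07 to 0.0251 in its other alternatives) and 0 lists were called. Leaving out 1 experiment gave 1355 to 2853 probe sets, with 456 to 1416 rises and 899 to 1437 falls. The lowest of each came without replicate 3, and the count without replicate 2 was 1909, while the 2853 without replicate 1 stayed within 1.5 times. Each of these fits holds fewer arrays, and for the fit without the experiment term the cause was not tested. IDI2, which never passed, ranged from -0.20 to 0.014, with the turn of sign without replicate 1. Of 149 genes under the naming rule that passed, 125 kept the call without the replicate block, 112 in all 3 fits that left out an experiment, and 0 with the methods' t-test, while none changed sign. Of the 3580 calls, 2359 were shared without the experiment term, 2490 without replicate 1, 1770 without replicate 2 and 1296 without replicate 3. Of the 18 lists called, 10 kept the call in each alternative but the estimated correlation, and 0 changed direction. Dropping the term also ended the camera calls of the basal list and of nuclear oxidative phosphorylation genes and of no other list, and the mevalonate list kept its call (adjusted p = 2.26e-06). Repeated quantile normalization and equal medians moved the median change of all probe sets by 0.02 and 0.04. Signal limits dim genes, as no measure of background accompanied the values here.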

Other observations

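The tests of doxycycline itself, of poly(A) tails and of experiment 1 were chosen only after the results were seen, as were the gene groups outside the 35 lists. CYP1A1, the largest rise given above, is a known target of the aryl hydrocarbon receptor AHR. Of 5 other probe sets of known AHR targets 3 rose and none fell. CYP1B1 rose by 1.36 (SE 0.13, 2.56-fold), TIPARP by 0.82 (SE 0.11, 1.76-fold) and ALDH3A1 by 0.66 (SE 0.099, 1.58-fold). NQO1 (0.21, SE 0.087) and CYP1A2 (0.13, SE 0.088) did not pass. The group was chosen because CYP1A1 rose, and no test of it as a list was run.

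GADD45G, a stress-induced gene, falls outside the naming rule and was singled out after its values were seen. Its RefSeq transcript is read by a probe set on chromosome 9, 91409440 to 91411290 (build 36), which rose 9.84-fold, from 8.02 ± 0.29 to 11.32 ± 0.27 (log2 change 3.30, SE 0.081, n = 3 each, limma adjusted p = 9.93e-06). A brighter probe set at 92018226 to 92018492 carries the same symbol through another sequence and went the other way, by -0.41 (adjusted p = 0.0173). Histone genes of the replication-dependent clusters were lower, with 50 of 72 probe sets down and none up, at a median of -0.78 (-0.31, -1.20 and -0.79 in experiments 1, 2 and 3). Among spliceosomal RNAs 11 of 17 probe sets fell and none rose (median -0.74, by experiment -0.30, -1.22 and -0.88). Mitochondrial probe sets under 120 bases, the length of tRNAs, had 9 falls among 16 and no rise (median -1.11, by experiment -0.49, -1.77 and -0.84). Those over 300 bases had 4 falls among 11 (median -0.34, by experiment -0.22, -0.69 and -0.16), and the lengths were not tested against each other. Experiment 2 had the largest fall in each of these groups.

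Sterol synthesis genes fell and ATF4 targets rose together, at medians of -0.65 and 0.47. Doxycycline itself, which is known to slow mitochondrial translation, may contribute to either change. 0 of the 6 arrays came from cells with doxycycline and without the p53 hairpin, so drug and hairpin cannot be told apart for these lists. An effect of the hairpin stays open beside it, untested.

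The fall of histones and spliceosomal RNAs, both without a poly(A) tail, could come from poorer recovery of such RNAs in treated cultures. Small nucleolar and Cajal body RNAs, also short and without a tail, give no decision. Those with a log2 level of at least 8 had a median of -0.026 over 94 probe sets (95% bootstrap interval -0.14 to 0.09, and 0.012 with equal array medians), against -0.78 for the histones. Of these 14 fell and 4 rose, and the median in experiment 2 was -0.31. Most lie in introns of host genes, whose RNA such probe sets can also read. Over 9 probe sets of tail-less RNAs with genes of their own, the median was -0.199 (interval -0.975 to 0.485), with SNORD3A at -1.15, SNORD13 at -0.97 and -0.81, and RN7SK at 0.03. Poorer recovery and other causes cannot be told apart with so few. Fewer cells in S phase is a candidate explanation for the histones alone. Replication-independent histones lay 0.62 above the replication-dependent ones (interval 0.387 to 0.854, two-sided permutation p = 0.00027 over 11 and 72 probe sets, which are not independent replicates), as that hypothesis needs. Their RNAs mostly carry a tail, however, so poorer recovery predicts the same gap and this test does not favour either. The spliceosomal and mitochondrial RNAs stay open.

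Experiment 1 changed less than the others, with a slope of 0.727 of its changes on the mean of experiments 2 and 3 over the 3580 called probe sets. An even dilution of all changes, as from untreated cells in the culture, would give each group of genes about this ratio. The 50 called histone probe sets had a median ratio of 0.408 (95% bootstrap interval over probe sets 0.323 to 0.468). That group was picked after its values were seen, and its large fall in experiment 2, for which poorer recovery stays open, lowers the ratio. Of the fixed lists, DNA replication genes lay below the slope (0.553, 0.513 to 0.715) and integrin genes above it (1.05, 0.797 to 1.55). Intervals of the other fixed lists with a ratio include the slope. The slope gives large changes more weight than a median ratio does. Over all called probe sets the median ratio was 0.765, and the interval of the ATF4 list lies below that value (0.617, 0.495 to 0.738). All these intervals take genes as independent, so they argue only weakly against dilution as the whole cause. The called mevalonate and sterol genes together had 0.949 (0.865 to 1.12), but with the lists apart the intervals include the slope (0.937, 0.697 to 1.10, and 0.991, 0.636 to 1.26). In the authors' workbook the columns whose values match experiment 1 carry a culture code of their own, whereas those of experiments 2 and 3 share a code up to its last letter. The labels do not explain the codes, so a difference between cultures stays open and untested.

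The 6 arrays allow 10 splits of 3 against 3, too few for a share under 0.05. The real split gave 3580 probe sets and 1 of 10 reached this, the highest other split giving 0. At an unadjusted p under 0.01 the real split gave 4160, again reached by 1 of 10, and the highest other gave 122. The other splits leave the doxycycline effect in their residual spread, which lowers both counts, so these contrasts are no evidence against chance. For the size of the mevalonate median, 5 of 10 splits were as large as 0.958, with 0.982 the highest. The 6 splits that part 1 pair of arrays differ from the real one, since with the experiment term they return the change of that pair alone. Among the other splits that part all 3 pairs the largest was 0.399. Each of these turns 1 pair against the rest, so part of the doxycycline change stays in its estimate. For the number of lists called by camera at the preset correlation, 18 was reached by 1 of 10. The highest other was 15, from splits that part 1 pair, and the others that part 3 pairs gave 5, 6 and 11. All of these still hold some of the doxycycline change, so they cannot show how often this test calls lists without an effect.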
